A study of Zea mays with 4 samples.

How the data were processed

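Per the labels, 15-day kernels were cross-linked with formaldehyde, nuclei were sonicated, and DNA was recovered with a rabbit antibody against recombinant full-length O11 before Illumina library preparation. The 4 libraries are 2 of WT and 2 of o11 mutant kernels, 1 of each per replicate number. Per the labels the WT library was the ChIP sample and the o11 library the control of 1 peak list per replicate, and replicates were not pooled. Bowtie2 2.3.2, MACS2 2.1.0 and the build B73 RefGen_v3 are named in the submitters' processing notes. Alignment filters, duplicate handling and the caller's settings are not given in the sources used here.

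The deposited lists give, per the file headers, the start, end, length and summit of each peak, the pileup (WT coverage signal at the summit) and the fold enrichment (a ratio of WT to control). A pair of the authors' deposited columns had their names damaged by a spreadsheet. From the values they are -log10 p and -log10 q, because the second equals the score in the summit list and the first equals a Poisson tail probability. Fold enrichment follows (pileup + 1) over (local o11 background + 1), so the o11 background of each peak was recovered as (pileup + 1) divided by the fold, minus 1. It is the value the fold was computed with, and need not be the o11 coverage at the summit. Several of the strongest replicate 1 peaks had the same value of 1.62, the lowest in that list. With the recovered background, the Poisson tail of the pileup matched the deposited -log10 p within 0.02 for 100% of replicate 1 peaks and 98.1% of replicate 2 peaks, leaving 310 unmatched. The lowest deposited -log10 q was 2.04 in replicate 1 and 2.05 in replicate 2. The shortest peaks were 245 and 213 bp.

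The steps between values show that the coverage signal in the authors' lists was scaled. WT pileups were whole numbers in replicate 1 and multiples of 0.857 in replicate 2, where 99.4% of values came within 0.005 of a whole number of steps. At peaks with a background of 10 or more, 79.9% of replicate 1 backgrounds came within 0.005 of a multiple of 0.943 and 88% of replicate 2 backgrounds within 0.005 of a multiple of 1. These steps are the ones that gave the highest share, and the backgrounds were derived from the deposited folds. The lists therefore hold scaled coverage, and library depth is unknown from them. Peak counts and fold levels of the 2 lists are not comparable as amounts of binding.

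Peaks were called shared when they overlapped the other list by at least 1 bp, and each replicate 1 peak was paired with the overlapping replicate 2 peak whose summit was nearest. Overlap was tested with 1000 circular shifts of the other list within each chromosome, one-sided. Summit distances were set beside those of 200 shifted lists. Correlations used 100000 two-sided permutations. Intervals are Wilson intervals for shares, exact Poisson intervals for folds (on unscaled WT reads) and percentile intervals of 1000 bootstrap draws for medians, all at 95%. Positions are 1-based. Regions were named by a rule fixed before the data were examined: the 10 shared peaks with the highest product of folds. All other regions named in the text were picked after their values were seen.

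Comparisons with genes, sequence motifs and short sequence words had been planned. They were not run, because no genome or annotation of B73 RefGen_v3 was used here and coordinates of different builds were not mixed. The planned test of counts per chromosome against chromosome length was replaced by a description in 1 Mb windows for the same reason, with chromosome lengths taken up to the last peak.

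Tests and measures chosen after the lists were seen were the log2 fold ratio between replicates, the contrast of the strongest with the weakest 10% of a list, and those of spacing between summits, of windows rich in unshared peaks, of mitochondrial peaks and of background levels. Spacing was compared with 1000 random placements of summits within their own 1 Mb windows. Windows of 1 Mb with at least 10 peaks were tested for more unshared peaks than the strength of their peaks gives (10 classes of fold), with an exact Poisson-binomial probability and Benjamini-Hochberg adjustment at 0.05, and dispersion over windows was compared with 2000 permutations within these classes. A first version of the window test took the probability of each window from the permutations, whose smallest value is 0.0005, and was replaced after its result had been seen.

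The code was tested on simulated data. With 60.4% of 14746 simulated peaks made to overlap, 60.5% were recovered, and a correlation of 0.5 was recovered as 0.501. A randomly placed list gave a shift p of 0.0594. The window test called 0 of 561 windows when no excess was planted, and with 10 planted windows it found 10 and called 1 other. The planted windows were chosen among fuller ones and were richer in unshared peaks than most windows called in the real lists. Simulated peaks were unshared independently of their neighbours. The simulation therefore does not show how the test does with weaker excesses or grouped peaks. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.

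Alternatives covered the overlap rule, a stricter q, the upper part of each list by fold, removal of the highest 1% by pileup, the numbered chromosomes alone, single replicates, and removal of peaks with a background of 10 or more. The last of these was added after the lists were seen.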

Results

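Opaque11 (O11) is a basic helix-loop-helix transcription factor of the maize kernel. Chromatin from kernels collected 15 days after pollination was precipitated with an antibody raised against O11 and sequenced (ChIP-seq). Wild-type kernels (WT) supplied 2 libraries, and kernels of the o11 mutant, described in the labels as lacking O11 protein, supplied 2 more as the negative control. The labels call the 2 replicates independent biological replicates made at different times. Each replicate is represented by 1 list of peaks in which the WT library stood above the o11 library of the same replicate number. The total number of reads per library is unknown from the lists, so the precision of a single peak is given by the reads stacked over its summit. Positions are those of B73 RefGen_v3.

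The comparison of WT with o11 asks where in the genome the antibody recovered more DNA when O11 was present. By the product of its folds in both replicates, the most enriched place was a 543 bp region of chromosome 2, from 184658451 to 184658993. Its WT pileup was 77 in replicate 1 over an o11 background of 1.89, and 136.25 in replicate 2 over a background of 1.00. In the authors' deposited tables this was a fold enrichment of 27.0 (exact Poisson interval 21.4 to 33.7) and of 68.6 (58.4 to 80.1). A region of chromosome 1 from 16791075 to 16791689 came next, with folds of 29.0 (23.7 to 35.1) and 54.6 (47.2 to 62.9). On chromosome 7 the region from 24190549 to 24191008 had folds of 30.9 (24.5 to 38.3) and 50.05 (41.1 to 60.4). Fold enrichments, here and throughout, are the authors' own values per peak. The Poisson intervals come from the WT reads alone at a fixed background, and like all intervals given here they cover counting error only.

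The 10 strongest shared regions, ranked by the product of their folds, lay on 6 chromosomes. Chromosome 1 held 3 of them, and the other 2 there were 52601510 to 52602226, with folds of 23.6 and 58.2, and 9163107 to 9163730, with folds of 24.4 and 46.2. Chromosome 2 held 2, the second being 44389553 to 44390260 with folds of 27.3 and 50.9. On chromosome 3 the regions 174802950 to 174803546 and 2626755 to 2628055 reached 24.6 and 23.6 in replicate 1, and 55.5 and 51.3 in replicate 2. Chromosome 9 had the region 13936421 to 13937210 with folds of 23.2 and 52.0. The weakest of these sites in replicate 2 was on chromosome 6, from 106212822 to 106213931, with folds of 29.0 and 38.3. At these 10 regions the o11 background stayed between 0.782 and 2.70, while the WT pileup ran from 60 to 103 in replicate 1 and from 81.4 to 165.38 in replicate 2. Several of the replicate 1 backgrounds were 1.62, the lowest that any peak of that list was given. The folds and ranks there depend in part on that value. Summits of the 10 regions in the 2 replicates were 2 to 108 bp apart. Which genes lie at these positions was not analysed here.

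Across the genome replicate 1 had 14918 peaks and replicate 2 had 16098, covering 6.67 and 6.35 Mb. The typical O11 peak was short: the median width was 376.5 bp (quartiles 293 and 518) in replicate 1 and 339 bp (266 and 459.75) in replicate 2. The median WT pileup was 22 and 22.28, over median o11 backgrounds of 2.96 and 2.0. The median fold enrichment in the authors' deposited tables was 5.42 (quartiles 4.44 and 7.08) and 7.69 (5.92 and 10.6). The single highest fold was 32.0 in replicate 1 and 68.6 in replicate 2.

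Most O11 regions recurred in the other replicate. Of the replicate 1 peaks, 9885 overlapped a replicate 2 peak by at least 1 bp, which was 66.3% (Wilson 95% interval 65.5 to 67.0). Of the replicate 2 peaks, 10073 overlapped a replicate 1 peak, which was 62.6% (61.8 to 63.3). When the other list was shifted at random along each chromosome, the overlap averaged 0.747% and 0.698% and never passed 1.03% and 0.981% in 1000 shifts. The one-sided permutation p was 0.000999 for each list, the smallest that 1000 shifts can give. Random shifts of only 5 to 50 kb, which keep the peaks in their neighbourhoods, gave averages of 1.34% and 1.26%, with the same p. Within shared regions the summits were a median of 43 bp apart (bootstrap interval 42 to 44, n = 9885 pairs), and 81.0% lay within 100 bp. Chance overlaps in the shifted lists had a median of 200 bp, with 25.8% within 100 bp.

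Strong sites were nearly all found in both replicates, and weak ones often in 1 list only. Among the strongest 10% of replicate 1, at folds from 9.43 up, 1481 of 1492 peaks were shared (99.3%, 98.7 to 99.6), against 37.2% (34.8 to 39.7) in the weakest 10%. In replicate 2 the strongest 10%, at folds from 15.1 up, had 1530 of 1610 shared (95.03%, 93.9 to 96.0), against 45.6% (43.2 to 48.0) in the weakest. The strongest region of replicate 1 with no partner was on chromosome 1, from 59659033 to 59659406, with a fold of 14.5 (10.3 to 19.8). In replicate 2 it was on chromosome 7, from 2429217 to 2429602, with a fold of 30.4 (23.4 to 38.8). These 2 regions were picked after their values were seen. The median fold of shared and unshared peaks was 6.13 and 4.59 in replicate 1, and 8.88 and 6.46 in replicate 2. Absence from a list means only that a region did not pass the authors' threshold there.

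**Figure D1:**
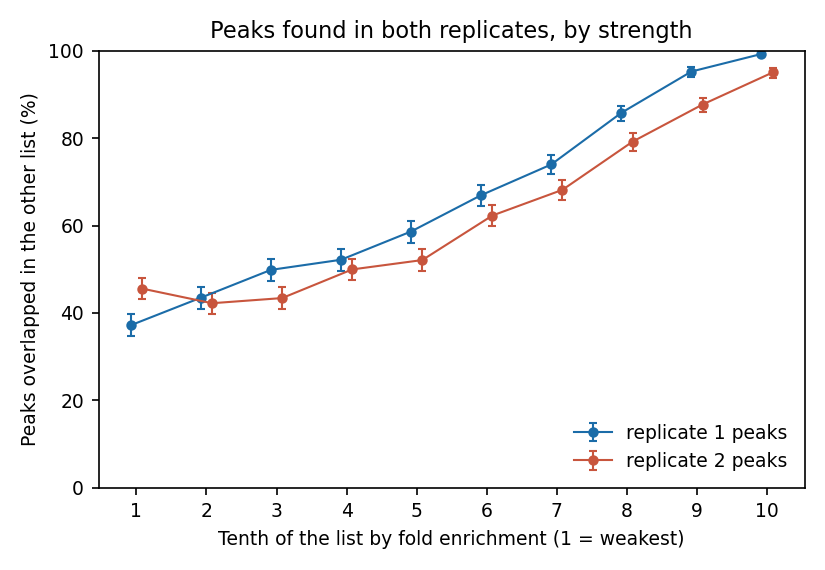
Percentage of peaks overlapped by at least 1 bp in the other replicate's list, against 10 equal classes of the list by fold enrichment (1 is the weakest), for replicate 1 (blue) and replicate 2 (red), with Wilson 95% intervals as bars. The share goes from 37.2% to 99.3% in replicate 1 and from 45.6% to 95.03% in replicate 2, whose weakest class lies above its next one at 42.2%.

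The order of strength carried over in part. Across the 9885 shared peaks, log2 fold enrichment had a Pearson correlation of 0.542 between replicates and a Spearman correlation of 0.498, each with a two-sided permutation p of 1e-05, the smallest that 100000 permutations can give. This is a correlation across peaks, which are not independent replicates. Fold enrichment was higher in replicate 2 at 8156 of these peaks (82.5%), by a median log2 ratio of 0.55 (bootstrap interval 0.53 to 0.56). At the same peaks the log2 ratio of WT pileup was 0.13 (0.12 to 0.14) and that of o11 background was -0.69 (-0.69 to -0.66). The lowest background that any peak was given was 1.62 in replicate 1 and 0.781 in replicate 2. Folds of the 2 lists thus rest on different backgrounds, and their ratio does not measure a change in binding.

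**Figure D2:**
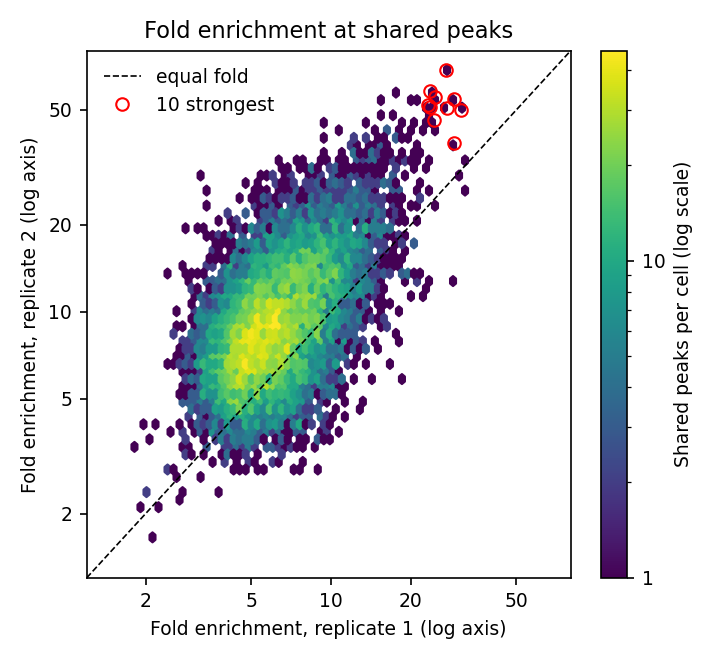
Fold enrichment of the 9885 shared peaks in replicate 1 (x, log axis) and replicate 2 (y, log axis), with colour giving the number of peaks per cell on a log scale, a dashed line at equal folds and red circles on the 10 strongest regions. Most of the cloud, 82.5% of the peaks, lies above the dashed line, and the circled regions lie between 23.2 and 30.9 in replicate 1 and between 38.3 and 68.6 in replicate 2.

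Taking 25% of the length as an end, O11 regions were denser than an even spread at the higher-coordinate end on 10 of 10 chromosomes. At the other end they were so on 4 only. This count depends on the width taken as the end. Over all 10 chromosomes the first 5% held 857 shared peaks and the last 5% held 946, while the part from 20% to 25% held 274. On 8 of 10 chromosomes the last 25% held more O11 regions than the first. Of the 9856 shared peaks on the 10 numbered chromosomes, 6860 lay in the outer 25% of the chromosome at either end (69.6%, 68.7 to 70.5), where an even spread would put 50%. The share was over 50% on 10 of 10 chromosomes, from 53.8% (50.3 to 57.2) on chromosome 4 to 79.0% (76.6 to 81.3) on chromosome 2. The last 25% of the chromosome alone held 42.0% (41.1 to 43.0) of the peaks, with an interval above 25% on 10 of 10 chromosomes. The first 25% held 27.6% (26.7 to 28.5), with an interval above 25% on 3 chromosomes (37.3% on chromosome 1, 42.4% on chromosome 2 and 30.5% on chromosome 5) and below it on 3 others. On chromosomes 1 and 2 the first 25% held more than the last, which had 32.0% (29.8 to 34.3) and 36.7% (33.9 to 39.5). The 3 low ones were chromosome 6 with 12.9% (10.7 to 15.5), chromosome 7 with 16.5% (14.2 to 19.2) and chromosome 10 with 20.2% (17.2 to 23.5). Chromosome 4 was also the sparsest, with 803 shared peaks or 3.32 per Mb, against 5.58 per Mb on chromosome 1, 5.40 per Mb on chromosome 5 and 4.79 per Mb over all 10. Lengths were taken up to the last peak of each chromosome. The Wilson intervals treat peaks as independent, and shared peaks were often grouped, so the intervals are likely too narrow. The longest stretches with no shared peak were 7.40 Mb on chromosome 9, from 51106355 to 58501921, and 7.11 Mb on chromosome 7, from 55207804 to 62318673. At the other extreme, the megabase of chromosome 6 from 164000001 to 165000000 held 31 shared peaks, and those of chromosome 5 from 6000001 and of chromosome 8 from 171000001 held 29 each. The median over 2062 such windows was 3, and 243 windows (11.8%) held none. How this distribution compares with that of genes or of mappable sequence was not analysed here.

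**Figure D3:**
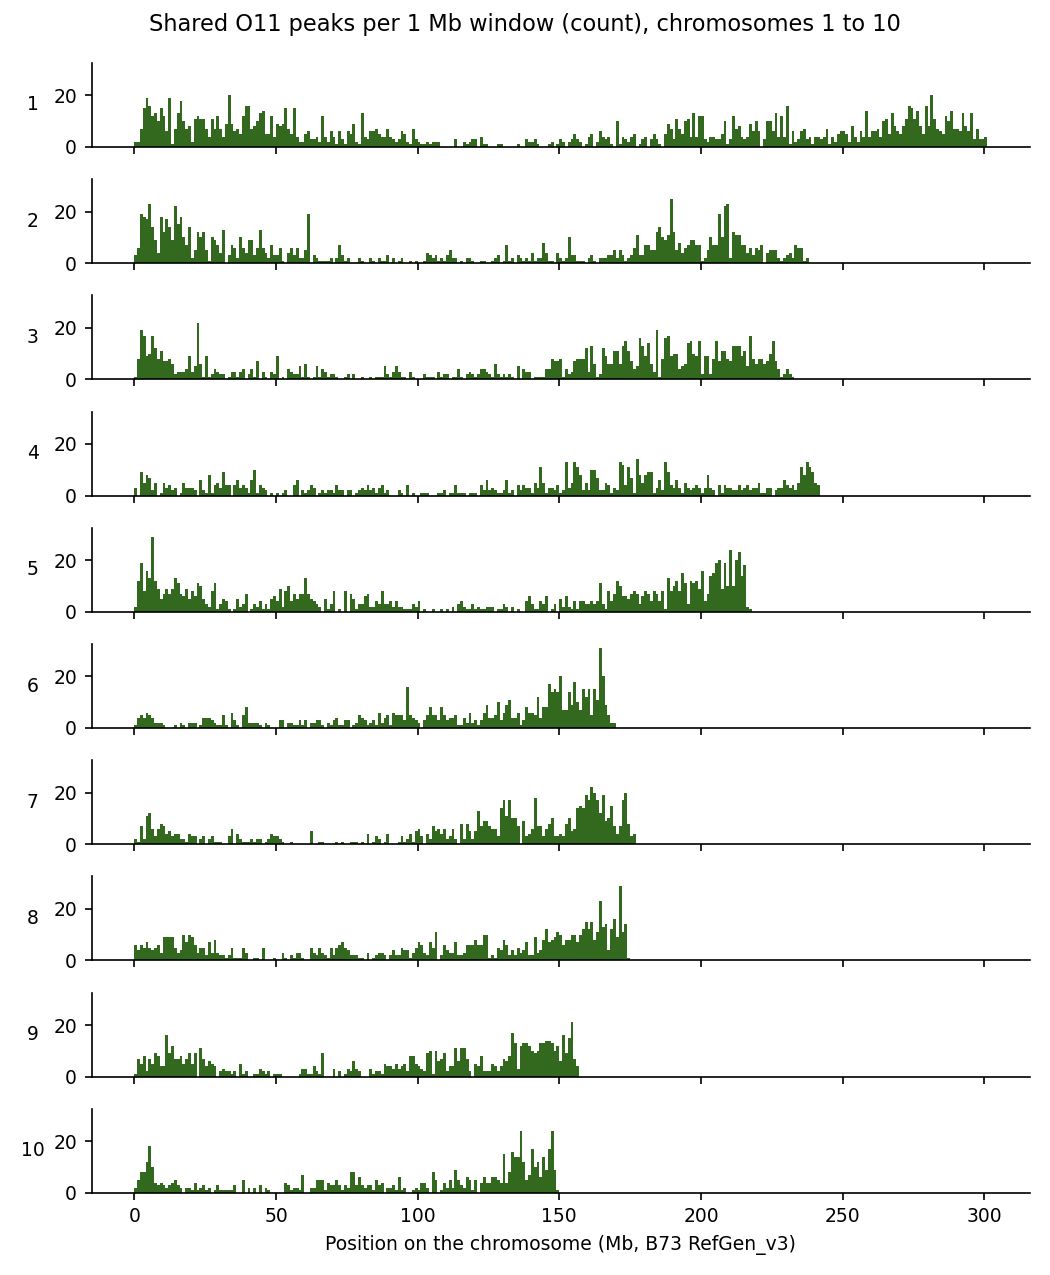
Number of shared O11 peaks in each 1 Mb window (y, count) along chromosomes 1 to 10 (x, position in Mb, B73 RefGen_v3). The last 25% of the chromosomes holds 42.0% of the peaks and the fullest window, with 31 on chromosome 6, while the first 25% of chromosome 6 holds 12.9% of its peaks, and stretches of 7.11 and 7.40 Mb on chromosomes 7 and 9 hold no shared peak.

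A small class of peaks had a high local o11 background, which need not be the o11 coverage at the summit. The o11 background was 10 or more at 299 peaks of replicate 1 and 50 of replicate 2, and of these 66 (22.1%, 17.7 to 27.1) and 35 (70.0%, 56.2 to 80.9) were shared. On the numbered chromosomes alone the class had 163 and 38 peaks, of which 54 (33.1%, 26.4 to 40.7) and 24 (63.2%, 47.3 to 76.6) were shared. The mitochondrial sequence held 118 of the replicate 1 peaks, 10 of them shared (8.47%), with a median fold of 2.04 over a median background of 63.5, and 11 of the replicate 2 peaks, with a median fold of 3.38 over 30. The plastid sequence held 6 peaks in replicate 1, with folds of 1.29 to 4.11, and 0 in replicate 2. Unplaced scaffolds held 48 and 31 peaks, of which 19 in each list were shared.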

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

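The log2 fold ratio, the contrast between the strongest and weakest 10% and the window counts, with their alternatives, and the removal of peaks with an o11 background of 10 or more were added after the data were seen, and the others were fixed before the data were examined. Across 80 alternative values, 66 kept their direction and side of the threshold, or stayed within their interval (for counts, within 1.5 times), and 14 moved further. The 66 include values that could not move, such as the outer 25% share on the numbered chromosomes alone, which the main setting already used. Overlap shares counted as kept when their p did, and several lay outside their main intervals. The overlap of the lists kept its p at the smallest value the shifts allow under every overlap rule, threshold and filter run, with 53.6% to 71.9% of replicate 1 peaks and 49.7% to 62.6% of replicate 2 peaks shared. The Pearson correlation of log2 fold stayed between 0.486 and 0.546. The Spearman correlation, 0.498 in the main setting, ranged from 0.411 in the upper 50% of each list to 0.504 with reciprocal overlap. The median summit distance fell to 40 bp with reciprocal overlap of at least 50%, to 33 bp with partners defined by summits within 100 bp (which removes longer distances by construction), to 40 bp at q below 1e-5 and to 36 bp in the upper 50% of each list. That last setting left 4719 shared peaks, since fewer peaks entered. The log2 fold ratio between replicates was 0.57 with reciprocal overlap and 0.62 in the upper 50%, and the cause was not tested. With all peaks of 1 replicate in place of shared peaks, 67.9% to 68.0% lay in the outer 25% at either end of the chromosomes. The count of windows rich in unshared replicate 1 peaks depended on the setting: from 10 it went to 6 in 2 Mb windows, 0 in 500 kb windows, 0 with partners by summit distance, 4 with strength taken from q, 6 with permutation probabilities and 11 without peaks of high background. Leaving out a replicate gives no value for results that need both lists. No paired analysis was possible because each list is already the WT library over the o11 library of the same replicate number. Alternatives for gene, motif and sequence-word results were not run, as those results were not computed. Library depth is unknown from the lists, so how it limits the calls was not measured.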

Other observations

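The tests of spacing, of unshared windows and of mitochondrial peaks were chosen after the lists had been seen, except the comparison at 2 to 5 kb, whose outcome was stated before it was computed. O11 regions often came in groups. The densest groups within 50 kb held 10 shared peaks each, on chromosome 2 with summits from 2058836 to 2104042 and on chromosome 6 from 164751160 to 164786682. In the chromosome 2 group the folds ran from 4.52 to 13.7 in replicate 1 and from 4.62 to 32.6 in replicate 2, and in the chromosome 6 group from 4.72 to 9.20 and from 3.82 to 17.2. A group of 9 lay on chromosome 2 from 61502280 to 61547555, and groups of 8 on chromosome 1 from 21682144 to 21722399 and on chromosome 5 from 6311200 to 6347467 and from 213315642 to 213352535. The 4 chromosomes with no region among the 10 strongest still had strong sites. Their best shared regions, picked after their values were seen, were 167009719 to 167010653 on chromosome 4 (folds 23.0 and 47.7), 2888888 to 2890038 on chromosome 5 (20.3 and 45.5), 5117713 to 5118669 on chromosome 10 (19.9 and 42.3) and 168495128 to 168495946 on chromosome 8 (16.2 and 41.1).

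Grouping of shared peaks was closer than their density per megabase gives. Neighbouring summits lay within 5 kb in 1680 of 9846 cases (17.1%), against an average of 4.004% and a highest of 4.75% in 1000 random placements within the same windows (one-sided permutation p = 0.000999, the smallest they allow), which argues against random placement at megabase density. Splitting of 1 broad region by the peak caller was tested at 2 to 5 kb, where the share was 7.60% against 2.37%, a ratio of 3.20. The outcome stated beforehand as speaking against splitting was thus met. Single shared peaks were up to 3661 bp wide in replicate 1 and 2636 bp in replicate 2, so a split region could also reach this range. The comparison therefore does not decide on splitting at any distance up to 5 kb. The ratio was 7.39 at 1 to 2 kb, 1.56 at 5 to 10 kb and 0.821 at 10 to 20 kb. Grouping by genes or by open chromatin may account for it but was not tested, and no biological explanation was tested.

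Unshared replicate 1 peaks were unevenly spread. In 561 windows their dispersion was 1.84, against at most 1.19 in permutations matched on fold (p = 0.0005, the smallest they allow). With strength taken from q it was 1.72, again against at most 1.19. Peak strength and chance for independent peaks thus do not give it. The permutations ignore grouping of peaks, which could also raise dispersion and was not tested. By the exact test 10 windows passed the adjusted threshold, with 157 of 209 peaks unshared against 80.2 given by strength (38 windows at an unadjusted p under 0.05). The first was 127000001 to 128000000 on chromosome 9 with 20 of 24. With strength taken from q 4 windows passed, of which 2 were among these 10. Replicate 2 was uneven too, with a dispersion of 1.25 against at most 1.198 in its permutations (p = 0.0005), but 0 of 624 windows passed the exact test, with 16 at an unadjusted p under 0.05. Lower o11 coverage or higher WT coverage in replicate 1 could produce windows such as its 10. At shared peaks inside against outside them the log2 differences were 0.025 (-0.14 to 0.10) for o11 background and 0.030 (-0.11 to 0.12) for WT pileup. Neither interval reaches the size set for a cause, but both pass slightly beyond the margin set for speaking against it. These limits were set after the lists were seen, and neither explanation is excluded. In the 6 windows of the replaced permutation version the differences were 0.10 (-0.02 to 0.37) and -0.02 (-0.29 to 0.07), which had spoken against both. Among unshared replicate 1 peaks of the tested windows, the median o11 background was 1.89 inside against 2.75 outside and the WT pileup 14 against 16. Over all replicate 1 peaks of these windows the medians were 1.89 against 2.83 and 15 against 22, so both were lower inside. Unshared peaks define the windows, so these values cannot decide on either explanation. Of the 10 windows 4 were on chromosome 9. On chromosome 8 the stretch from 130 to 138 Mb around its windows (3 Mb to either side) was picked after its values were seen. There 82 of 116 replicate 1 peaks were unshared (70.7%), against 33.2% over the numbered chromosomes, a comparison not matched on strength. Of its 63 replicate 2 peaks 44.4% were unshared, while 62.6% of replicate 2 peaks over the numbered chromosomes were shared. With 0 to 11 windows across settings, which windows are involved is uncertain, and no biological explanation was tested.

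Mitochondrial peaks were many in replicate 1 and few in replicate 2, but 10 of the 11 in replicate 2 overlapped replicate 1 peaks, against a mean of 2.24 and a highest of 10 in random shifts (one-sided permutation p = 0.0016), which argues against random positions. A general excess of mitochondrial DNA in the WT library of replicate 1 may underlie the other peaks there; peaks covered 14.0% of the sequence, and since regions under the threshold are not listed, this cannot decide. The 2 largest stretches of high-background peaks on the numbered chromosomes had 10 on chromosome 4 from 172409453 to 172455490, with a median o11 background of 150.4 and 0 shared, and 9 on chromosome 1 from 234529160 to 234689357, with a median of 289.5 and 1 shared, whereas the next, on chromosome 6 from 39159060 to 39283540, had 6 of 7 shared at backgrounds of 14.1 to 72.6. The first 2 medians lie above the lowest plastid peak at 48.1, so reads shared with organelle sequence remain open, and the sequence itself was not used here. No biological explanation was tested.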
